A study of Mus musculus with 5 samples.

How the data were processed

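RNA from whole tibio-femoral joints was extracted with Trizol and silica columns, labelled with biotin by in-vitro transcription and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values were signal intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes, whose version and scaling target are not given in the sources used here. The 5 arrays came as 2 tables, 1 per array type, with the same 22690 probe sets. All values were positive, and the 2% trimmed mean was close to 250.1 on each array, as it is when each array is scaled on its own. No detection calls were used, so signal over background was judged from the 27 Bacillus control probe sets, which have no target in mouse RNA. There are 2 wildtype and 3 double-null pools, from separate animals.

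Both tables held both genotypes, so the table, called array type, entered the fit as an additive term. Values were transformed as log2(signal + 32) and quantile normalised over the 5 arrays. Of all probe sets, 20393 had 1 gene symbol in the platform annotation, 691 had several, 1606 had none (64 of all probe sets were array controls), and 20364 symbols were updated through Entrez numbers to the GRCm38.p6 gene table. Each of 12394 genes was represented by its brightest probe set over all 5 arrays, and the 7436 genes with a mean above the 40th percentile, a signal near 98.5, were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, 2 residual and 9.85 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The targeted genes were fitted over all 22626 probe sets other than controls, without the filter, so an adjusted p for Bgn differs between the 2 fits. Groups were called apart on the normalised scale. Means ± SD are of deposited signals, and SE belongs to the fitted log2 fold change.

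Gene lists were tested with limma's camera on the same fit, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one, and adjusted over the 18 of 20 lists with at least 5 measured members. The T and NK cell list (4 measured) and the skin list (1 measured) were not tested. Of the 18 lists, 8 passed with the preset correlation, 4 upward and 4 downward, and 0 with the estimated one. The estimated correlation ran from -0.065 for the erythroid list to 0.72 for the osteoclast list. Where genes correlate more than the preset value, the preset p is too small. Lists, tests, settings and the rule for named genes were fixed before the data were examined. The rule took Epyc and Bgn, then up to 12 genes per direction past the threshold with groups fully apart. Directions with fewer were filled to 8 with the most changed genes whose groups were apart, as values only. From each list it took up to 4 members with the smallest p. It named 85 genes, and 2 genes without an approved symbol were skipped in the filling. Of the named genes 31 had over 1 probe set above the filter, and in 7 of them (Adamts5, Btg2, Ccna2, Gpaa1, Ltbp3, Mef2c and Scd1) these differed in sign. Correlations between arrays are across genes, which are not independent replicates.

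The fit was tested on simulated data for the double-null against wildtype comparison of 7436 genes, in 10 draws with the fitted means and moderated variances. Noise was normal and independent between genes, and 100 genes were changed at each size. The fit recovered 97.5% of genes changed by 1 and 100% of those changed by 2 on the log2 scale, with 16.7 false calls per draw, or 7.8% of calls. Moderated variances scatter less than measured ones, so these rates check the code and do not give the power on the measured arrays. A list moved by 0.5 was called in 10 of 10 draws with the preset correlation and in 0 of 10 with the estimated one. With 2 residual degrees of freedom the estimated correlation thus missed a shift that was present. Genes without correlation favour the preset value, so the draws cannot show that it holds for the measured lists.

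Alternatives were the deposited scaling, median centring, pseudocounts of 1 and 128, no filter and a filter at the 60th percentile. The fit was also run without the array-type term, on array type B alone, with a replicate block, without the intensity trend, with the mean over a gene's probe sets, and without each array in turn. Neighbouring genes were taken within 10 Mb by start position, and shares were compared with Fisher's exact test. Intervals on medians came from 10000 bootstrap draws over genes and describe the spread between genes, not between animals.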

Results

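Knee joints of male mice were compared between wildtype animals and animals lacking both epiphycan (Epyc) and biglycan (Bgn), to ask which transcripts differ in the joint when these 2 small leucine-rich proteoglycans are missing. Epiphycan is a proteoglycan of epiphyseal cartilage, and biglycan is a proteoglycan of bone, cartilage, tendon and other connective tissues. The mice were 3 months old and of a mixed C57 and 129 background. Each of the 5 arrays held RNA from whole tibio-femoral joints of 3 mice, 6 joints in all, so a replicate was a separate pool of animals. There were 2 wildtype and 3 double-null pools. Their Affymetrix values came as 2 tables with the same 22690 probe sets, treated here as 2 array types: wildtype pool 2 and double-null pool 3 as type A, and wildtype pool 1 and double-null pools 1 and 2 as type B. The tables belong to 2 platform records. Whether the arrays themselves or a batch differed, or only the record, is not given in the sources used here. Signals ran from 0.0423 to 26173, with a 2% trimmed mean close to 250.1 on each array. Group differences below are log2 fold changes, double-null over wildtype, on the log2(signal + 32) scale with array type as a term. That scale understates the change of dim genes, and the number of arrays limits the precision throughout.

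The targeted genes were examined first, as a check of the labels. Bgn fell in the double-null joints on each of its 3 probe sets. The least reduced probe set read 2708 ± 997 in the wildtype pools (mean signal ± SD, n = 2) and 211 ± 11.1 in the double-null pools (n = 3), a log2 fold change of -3.48 with limma adjusted p = 0.0034 over 22626 probe sets. Another read 3210 ± 1207 against 20.9 ± 21.6 (-6.00, adjusted p = 0.0047), and the remaining one read 3020 ± 1408 against 46.1 ± 29.0 (-5.42, adjusted p = 0.00062). The residual signal of 211 lay above the highest of the 27 Bacillus control probe sets on any array, 63.5, while the double-null means of the other Bgn probe sets lay below it. The fold changes of those 2 therefore depend on the added constant and are not exact sizes: over all alternatives they ran from -7.71 to -4.48 and from -6.47 to -4.19, against -3.77 to -3.05 for the first. Epyc had a single probe set, which was dim in whole joints. Its signal was 85.0 ± 8.79 in wildtype and 5.17 ± 5.02 in double-null pools, with 1.29 to 10.8 on the 3 double-null arrays, inside the range of the Bacillus controls. The log2 fold change of Epyc, -1.64 ± 0.19 (SE), missed the threshold over all probe sets (limma unadjusted p = 8.0e-05, adjusted p = 0.16). It ran from -4.24 to -0.67 over all alternatives, so it is not an exact size either. Whether these probe sets lie inside the deleted parts of the genes is not given in the sources used here. With array type B alone, or without wildtype pool 1, wildtype pool 2 or double-null pool 3, 0 of the 4 targeted probe sets passed. The Bgn fold changes without single pools stayed between -6.26 and -3.16.

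**Figure D1:**
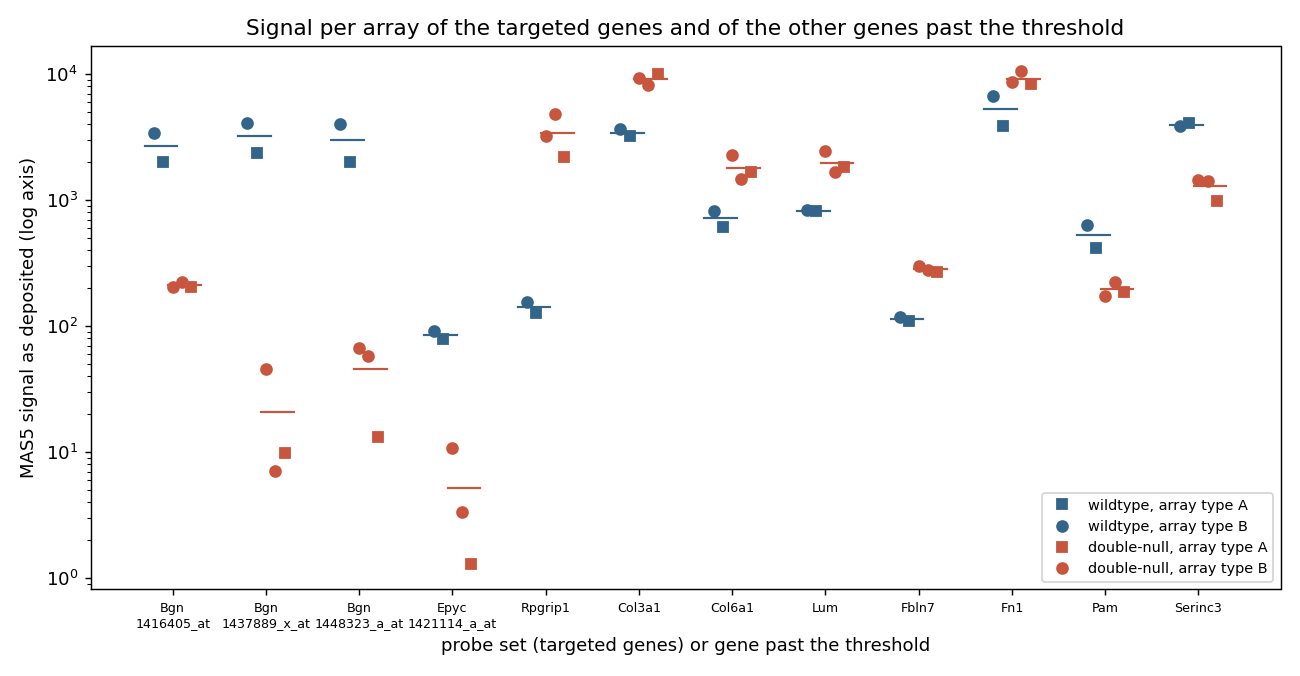
Deposited MAS5 signal (log axis) on each of the 5 arrays for the 4 probe sets of Bgn and Epyc and for the 8 other genes past the threshold; points are pools, colours give genotype, shapes give array type, and short lines give group means. For each of these genes every double-null point lies on 1 side of both wildtype points, as for Col3a1, at 3439 in wildtype and 9159 in double-null pools.

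Outside the targeted genes, the double-null joints had more message for several extracellular matrix proteins. Col3a1, the fibrillar collagen of type III fibres, rose 2.76-fold (log2 fold change 1.46 ± 0.16 SE), from 3439 ± 307 to 9159 ± 963. Col6a1, a chain of the microfibrillar collagen VI, rose 2.35-fold, from 716 ± 150 to 1808 ± 412. Lum, encoding lumican, a proteoglycan of the same family as biglycan that binds collagen fibrils, rose 2.28-fold, from 827 ± 14.0 to 1985 ± 404. Fbln7, encoding the adhesion protein fibulin 7, rose 2.19-fold, from 114 ± 5.96 to 283 ± 17.8. Fn1, encoding fibronectin, rose 1.77-fold, from 5291 ± 2041 to 9237 ± 1257. Of these, Col3a1 and Col6a1 belong to the fibrous matrix list tested below, Lum to the proteoglycan list, and Fbln7 and Fn1 to none. They were not tested as a group of their own, and Lum lies within 10 Mb of Epyc. The adjusted p was 0.0025 for Col3a1, 0.040 for Lum and for Fbln7, 0.043 for Fn1 and 0.043 for Col6a1 (limma, Benjamini-Hochberg over 7436 genes). Across the alternative settings Col3a1 passed in 10 of 16, Fbln7 in 7 of 15, Lum in 5 of 16, Fn1 in 4 of 16 and Col6a1 in 3 of 16.

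Rpgrip1, Serinc3 and Pam, the other genes past the threshold besides Bgn, do not encode joint matrix proteins. Rpgrip1, encoding a protein of the photoreceptor connecting cilium, rose 18.1-fold, from 141 ± 20.1 to 3432 ± 1330 (log2 fold change 4.17 ± 0.21, limma adjusted p = 1.2e-06). Its 3 other probe sets lay below the intensity filter, at log2 fold changes of 0.44, 0.18 and -0.24. Serinc3, a membrane protein of the serine incorporator family, fell from 3970 ± 154 to 1287 ± 255 (-1.70 ± 0.18, adjusted p = 0.0021). Pam, the enzyme that amidates peptide hormones, fell from 528 ± 156 to 196 ± 27.1 (-1.31 ± 0.19, adjusted p = 0.024). Rpgrip1 passed in 14 of 15 alternatives, Serinc3 in 10 of 16 and Pam in 9 of 16.

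In all, 9 of 7436 genes passed the threshold, 6 higher and 3 lower in the double-null pools, and each of the 9 had every double-null array on 1 side of both wildtype arrays. On array type A alone the log2 differences were 3.87 for Rpgrip1, 1.61 for Col3a1, 1.44 for Col6a1, 1.16 for Lum, 1.10 for Fbln7, 1.04 for Fn1, -3.15 for Bgn, -2.09 for Serinc3 and -1.05 for Pam. On array type B alone they were 4.41, 1.35, 1.08, 1.21, 1.15, 0.67, -3.72, -1.40 and -1.51 in the same order, so all 9 had 1 sign on both types. At unadjusted p under 0.05 there were 460 genes, 263 higher and 197 lower, where 371.8 would be expected by chance. Every double-null array lay above both wildtype arrays for 703 genes (9.45%) and below both for 759 (10.2%), against 10% expected by chance in each direction. A split of 2 against 3 has 10 arrangements, so an exact permutation test of 1 gene could not go below 0.1. With the deposited scaling 5 genes passed, 2 higher and 3 lower, and with median centring 6 passed, 3 higher and 3 lower. Rpgrip1 and Bgn alone passed without wildtype pool 1, wildtype pool 2 or double-null pool 3, while 18 genes passed without double-null pool 1 and 52 without double-null pool 2. Without the array-type term 4 genes passed, and without the intensity filter 2 passed. Because an array left alone on its type is fitted exactly, leaving out wildtype pool 2 or double-null pool 3 gives the same contrast as array type B alone, and leaving out wildtype pool 1 gives that of array type A alone, so these are not separate checks.

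Genes that missed the threshold but had their groups fully apart on the normalised scale are given as values. Higher in the double-null pools were Col6a2, at 1450 ± 390 against 635 ± 174 (log2 fold change 1.13), and Pnrc2, a nuclear receptor coactivator, at 725 ± 200 against 331 ± 171 (1.11). The size depended on array type, at 1.75 on type A and 0.66 on type B for Col6a2, and 0.16 and 1.83 for Pnrc2. Lower were Gpaa1, of the GPI anchor attachment complex, at 817 ± 285 against 1411 ± 555 (-0.94), and Ddit4, a stress-induced inhibitor of mTOR signalling, at 326 ± 109 against 640 ± 95.2 (-0.92). Gpank1 (-0.87), Adat2 (-0.84) and the class II histocompatibility gene H2-Ab1 (-0.83) followed. On types A and B these were -1.34 and -0.52 for Gpank1, -0.55 and -1.06 for Adat2, and -0.29 and -1.23 for H2-Ab1. The deposited signals of Gpaa1 overlapped between groups. Gpaa1 had other probe sets at -0.16 and 0.83, Gpank1 had a second at -0.049, and H2-Ab1 had others at -0.44 and -0.040, so their values rest on the brightest probe set.

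The list of tendon, ligament and fibrous matrix genes shifted upward as a group with the preset correlation between genes, though not with an estimated one. Of its 17 measured members 15 had positive log2 fold changes, with a median of 0.58, 2 rose past the threshold over all genes, 10 passed adjusted over the list alone, and 11 lay above both wildtype arrays on every double-null array. Besides Col3a1 and Col6a1, the members with the smallest p were Thbs4, a thrombospondin of tendon matrix (661 ± 32.2 against 316 ± 51.9, log2 fold change 1.02), and Tnmd, encoding tenomodulin, a marker of mature tendon cells (286 ± 55.2 against 140 ± 60.2, 1.03). Both missed the threshold over all genes (adjusted p = 0.054 and 0.10). The camera test of the list gave adjusted p = 1.4e-14 with a preset correlation of 0.01 between genes, and adjusted p = 0.45 with an estimated correlation of 0.23. If the genes correlate near the estimate, the smaller p overstates the evidence. The median shift was 0.69 on array type A and 0.50 on array type B. It stayed between 0.51 and 0.70 without any single pool, past the threshold each time.

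Small leucine-rich proteoglycans other than the targeted genes also leaned upward. Of 9 measured members 8 had positive values and Bgn alone was negative, which left a median of 0.37 but a mean of 0.088. Lum rose, and Aspn (asporin, 398 ± 91.9 against 177 ± 22.4, log2 fold change 1.06) passed adjusted over the list alone, at adjusted p = 0.093 over all genes. Ogn (osteoglycin) read 560 ± 186 against 350 ± 54.9, at 0.59, with 0.25 on array type A and 0.84 on array type B. A second probe set of Ogn was at 0.14, while that of Aspn was at 1.09. The list gave camera adjusted p = 0.0041, and adjusted p = 0.51 with an estimated correlation of 0.22. Without the intensity filter it did not pass (median 0.26, adjusted p = 0.37). Its members Lum and Dcn lie within 10 Mb of Epyc. The shift was 0.62 on array type A and 0.12 on array type B, and it was 0.13 without wildtype pool 2 and 0.11 without double-null pool 3, no longer past the threshold (adjusted p = 0.36 and 0.40), nor on array type B alone (0.12, adjusted p = 0.40).

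**Figure D2:**
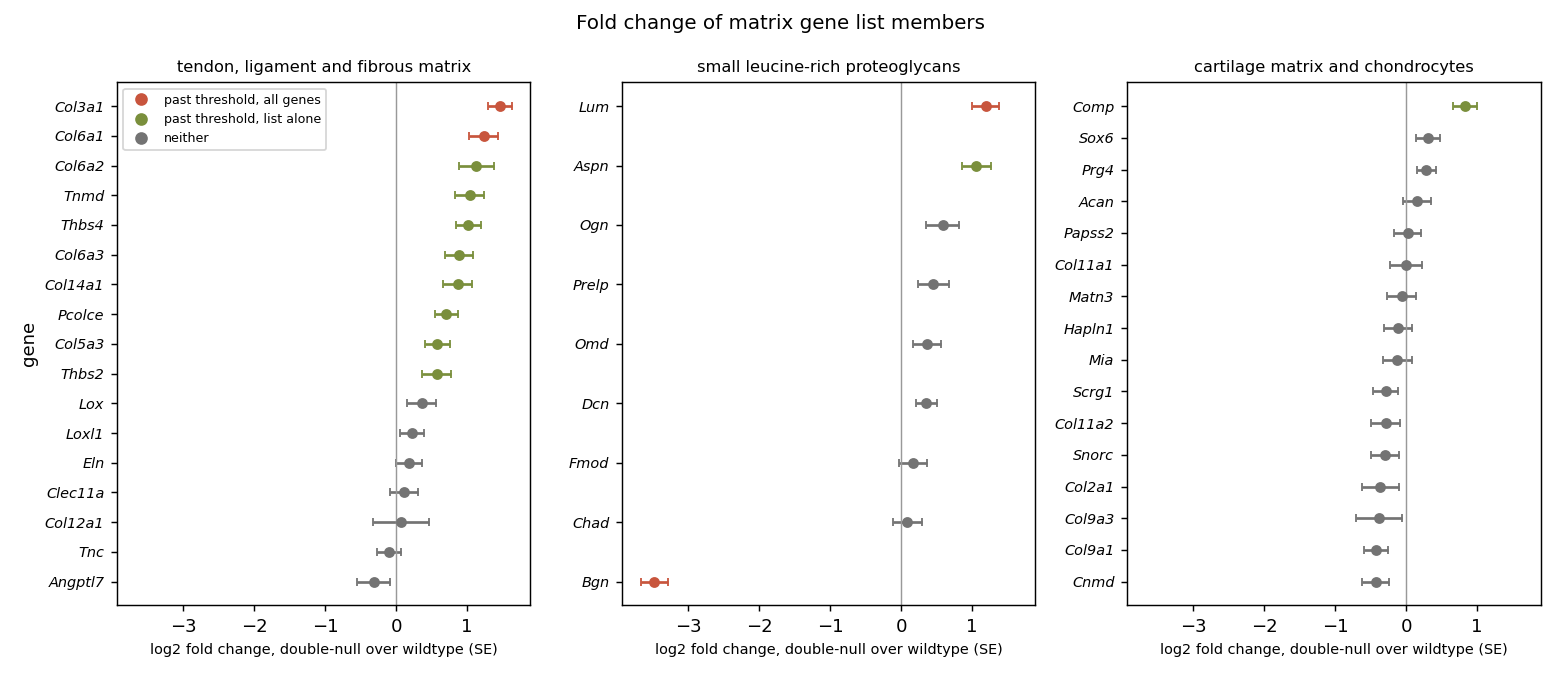
Log2 fold change, double-null over wildtype, of each measured member of 3 gene lists (fibrous matrix, small leucine-rich proteoglycans, cartilage matrix); bars are SE, and colours mark members past the threshold over all genes, over the list alone, or neither. In the fibrous list 15 of 17 members lie above 0, and in the cartilage list 5 of 16.

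The cartilage list did not move as a group. Of its 16 measured members 5 had positive and 11 negative values, with a median of -0.12 (camera adjusted p = 0.52). Comp, a pentameric glycoprotein of cartilage and tendon, read 4367 ± 704 against 2423 ± 614 (log2 fold change 0.83) and passed adjusted over the list alone, at adjusted p = 0.11 over all genes. Col9a1 (826 ± 64.8 against 1069 ± 215, -0.42) and Cnmd, encoding chondromodulin (426 ± 12.5 against 579 ± 148, -0.43), lay lower and did not pass. Prg4, encoding the joint lubricant lubricin, was at 0.28. The median of the list was 0.28 on array type A and -0.40 on array type B. Without wildtype pool 1 it was 0.30 (adjusted p = 0.0021), and without wildtype pool 2 or double-null pool 3 it was -0.40 (adjusted p = 0.0051 and 0.0050), so its direction differed between the array types, each with a single wildtype pool, and cannot be assigned to a pool or to the type.

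Genes of hypertrophic cartilage and of osteoblasts gave no group shift. The hypertrophic list had a median of -0.019 over 11 members (camera adjusted p = 0.53), with Pth1r, the parathyroid hormone receptor of growth plate and bone, at -0.52, Mef2c at -0.33, Gli1 at -0.28 and Col10a1 at 0.48. Medians were 0.074 on array type A and -0.16 on array type B, and Col10a1 itself was at -0.40 on array type B alone. The osteoblast and osteocyte list had a median of -0.0044 but a mean of 0.13 and an upward test, which did not pass (adjusted p = 0.097). Its medians were 0.0038 on array type A and 0.064 on array type B, and without double-null pool 2 it passed (0.040, adjusted p = 0.032). Within it 3 members passed adjusted over the list alone and none over all genes: the collagen V chain gene Col5a2 (4494 ± 478 against 3048 ± 715, 0.54), the podoplanin gene Pdpn (298 ± 39.5 against 174 ± 23.9, 0.70) and the periostin gene Postn (1237 ± 361 against 741 ± 229, 0.76). The related Col5a1 was at 0.35.

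Osteoclast genes shifted downward in the fit of all 5 arrays, but not on array type A. Their level was 0.36 in wildtype pool 1 and -0.11 in wildtype pool 2, against -0.15, -0.021 and -0.11 in double-null pools 1 to 3. All 8 measured members had negative values, with a median of -0.24 (camera adjusted p = 0.0041, and adjusted p = 0.65 with an estimated correlation of 0.72). None passed over all genes, and Acp5, the tartrate-resistant acid phosphatase of osteoclasts, passed adjusted over the list alone (1952 ± 165 against 3334 ± 1475, log2 fold change -0.73), at -0.22 on array type A and -1.10 on array type B. The proton pump subunit gene Tcirg1 was at -0.38, the gelatinase gene Mmp9 at -0.28 and the chloride channel gene Clcn7 at -0.26. The shift was 0.024 on array type A and -0.42 on array type B. Without wildtype pool 1 it was -0.031 (adjusted p = 0.88), and without double-null pool 1 it was -0.14 (adjusted p = 0.055).

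Matrix-degrading enzymes with their inhibitors, and TGF-beta and BMP signalling genes, shifted upward by smaller amounts. The enzyme list had a median of 0.16 over 16 members, 12 of them positive (camera adjusted p = 0.016, and adjusted p = 0.46 with an estimated correlation). Htra1, a secreted serine protease (867 ± 134 against 401 ± 51.2, log2 fold change 1.01), and Mmp3, stromelysin 1 (158 ± 24.7 against 59.7 ± 14.1, 1.06), passed adjusted over the list alone, with adjusted p = 0.054 and 0.10 over all genes. The mean wildtype signal of Mmp3 lay below the highest Bacillus control on any array, 63.5. Its signals of 69.6 and 49.7 in wildtype pools 1 and 2 lay above the highest controls on those arrays, 38.5 and 36.3. The signal was still low, so its fold change depends on the added constant and ran from 0.61 to 1.41 over alternatives. Mmp2 was at 0.58, and the aggrecanase gene Adamts5 was at -0.49 on its brightest probe set and at 0.022 on its second. The signalling list had a median of 0.13 over 23 members, 15 of them positive (adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation). The activin subunit gene Inhbb was at 1.30, with overlapping groups, and passed adjusted over the list alone. Its mean wildtype signal of 61.2 also lay below the highest Bacillus control on any array, with 29.5 in wildtype pool 1 and 93.0 in wildtype pool 2. Its value ran from 0.71 to 1.80 over alternatives, and its other probe set, below the filter, was at 0.12. Gdf10 was at 0.75 (0.11 on array type A and 1.23 on array type B), Ltbp3 at 0.49 with a second probe set at -0.30, and Inhba at -0.42.

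Both of these shifts were small on either array type. The enzyme list moved by 0.21 on type A and 0.15 on type B, and the signalling list by 0.15 and 0.12. The enzyme call ended without wildtype pool 2 (0.15, adjusted p = 0.57) and without double-null pool 3 (0.15, adjusted p = 0.58), on array type B alone (adjusted p = 0.57) and with the filter at the 60th percentile (adjusted p = 0.14). The signalling call ended without wildtype pool 2 (0.12, adjusted p = 0.25), double-null pool 2 (0.13, adjusted p = 0.062) or double-null pool 3 (0.11, adjusted p = 0.41), and without Inhbb (0.12, adjusted p = 0.071), a choice made after the values were seen. It also ended without the filter (adjusted p = 0.10), with the filter at the 60th percentile (adjusted p = 0.18), with the mean over probe sets (adjusted p = 0.065) and on array type B alone (adjusted p = 0.41), and it passed in 8 of 18 alternatives.

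Whole joints carry marrow, muscle, fat and vessels, and marker lists of some of these differed between the groups with the preset correlation only. Neutrophil and granulocyte precursor genes shifted downward, with 16 of 18 members negative and a median of -0.19 (camera adjusted p = 0.00085, and adjusted p = 0.45 with an estimated correlation). The colony-stimulating factor receptor gene Csf3r was at -0.48, Ms4a3 at -0.42, the cathepsin G gene Ctsg at -0.37 and the neutrophil elastase gene Elane at -0.32, and no member passed. These 4 had the smallest p, and other members hardly moved, with S100a8 at 0.0048, S100a9 at -0.0048 and Ngp at -0.0061. Mpo was at -0.077, Ltf at -0.090 and Camp at -0.099. Medians were -0.13 on array type A and -0.27 on array type B, and between -0.29 and -0.12 without single pools. Fat cell genes had a median of -0.27, with 8 of 10 negative (adjusted p = 0.0041, and adjusted p = 0.45 with an estimated correlation). The members with the smallest p were the triglyceride lipase gene Pnpla2 (-0.46), the fatty acid binding protein gene Fabp4 (-0.38), Dgat2 (-0.33) and Scd1 (-0.31). No member passed, and the fat cell markers Adipoq (0.058) and Lpl (0.036) lay slightly above 0. Other probe sets above the filter were at -0.21, -0.065 and -0.056 for Fabp4, -0.21 for Dgat2 and 0.13 for Scd1. Medians were -0.17 on type A and -0.34 on type B, and the call ended without wildtype pool 1 (-0.17, adjusted p = 0.22) or double-null pool 2 (-0.21, adjusted p = 0.069). Wildtype pool 1 had the highest level of the osteoclast (0.36), neutrophil (0.21) and fat (0.21) lists alike.

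Skeletal muscle genes differed far more between arrays than between genotypes. The list median on each array, relative to the gene means, was 0.56 in wildtype pool 2 and 0.67 in double-null pool 3, both on array type A, and -0.26, -0.18 and -0.73 in wildtype pool 1 and double-null pools 1 and 2 on type B. With array type in the fit, 17 of 21 members were negative with a median of -0.15 (camera adjusted p = 0.017, and adjusted p = 0.70 with an estimated correlation), and 0 members had their groups apart. Myh2 was at -0.59, Ckm at -0.45, Tcap at -0.39 and Acta1 at -0.32. The shift was 0.15 on type A and -0.26 on type B. Without the array-type term it was -0.31 (adjusted p = 0.0063). It turned to 0.15 without wildtype pool 1 and to 0.0052 without double-null pool 2 (adjusted p = 0.88 in both), and it did not pass with the deposited scaling (-0.12, adjusted p = 0.17) or median centring (-0.087, adjusted p = 0.14), nor without the filter (adjusted p = 0.067).

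The remaining lists did not pass. Endothelial and vessel wall genes had a median of 0.082 (camera adjusted p = 0.065), with Pdgfrb at 0.59, Tagln at 0.37, Rgs5 at 0.34 and Vwf at 0.17. Their medians were 0.33 on array type A and -0.041 on type B, and they passed without wildtype pool 1 (0.33, adjusted p = 0.0012) or double-null pool 2 (0.13, adjusted p = 0.032). Immediate early and stress genes had a median of 0.072 (adjusted p = 0.31), led by Fos at 0.70, with -0.017 on type A and 0.15 on type B. Macrophage genes were at 0.016 (adjusted p = 0.61, 0.058 on type A and 0.020 on type B), with Cd14 at 0.49 and Mrc1 at 0.43. B lymphocyte genes were at -0.035 (adjusted p = 0.52, -0.076 on type A and -0.017 on type B), with Dntt at 0.57 and Cd22 at -0.42. Erythroid genes were at -0.043 (adjusted p = 0.61, -0.039 on both types), with Add2 at -0.35 and Ermap at 0.23. Inflammatory and osteoarthritis-associated genes were at -0.039 (adjusted p = 0.71, -0.023 on type A and -0.082 on type B), with Ccl5 at -0.37 and Icam1 at 0.30. Cell division genes had a median of 0.030 but a mean of -0.012 and a downward test (adjusted p = 0.92, -0.012 on type A and 0.027 on type B), which turned upward under the deposited scaling and median centring.

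**Figure D3:**
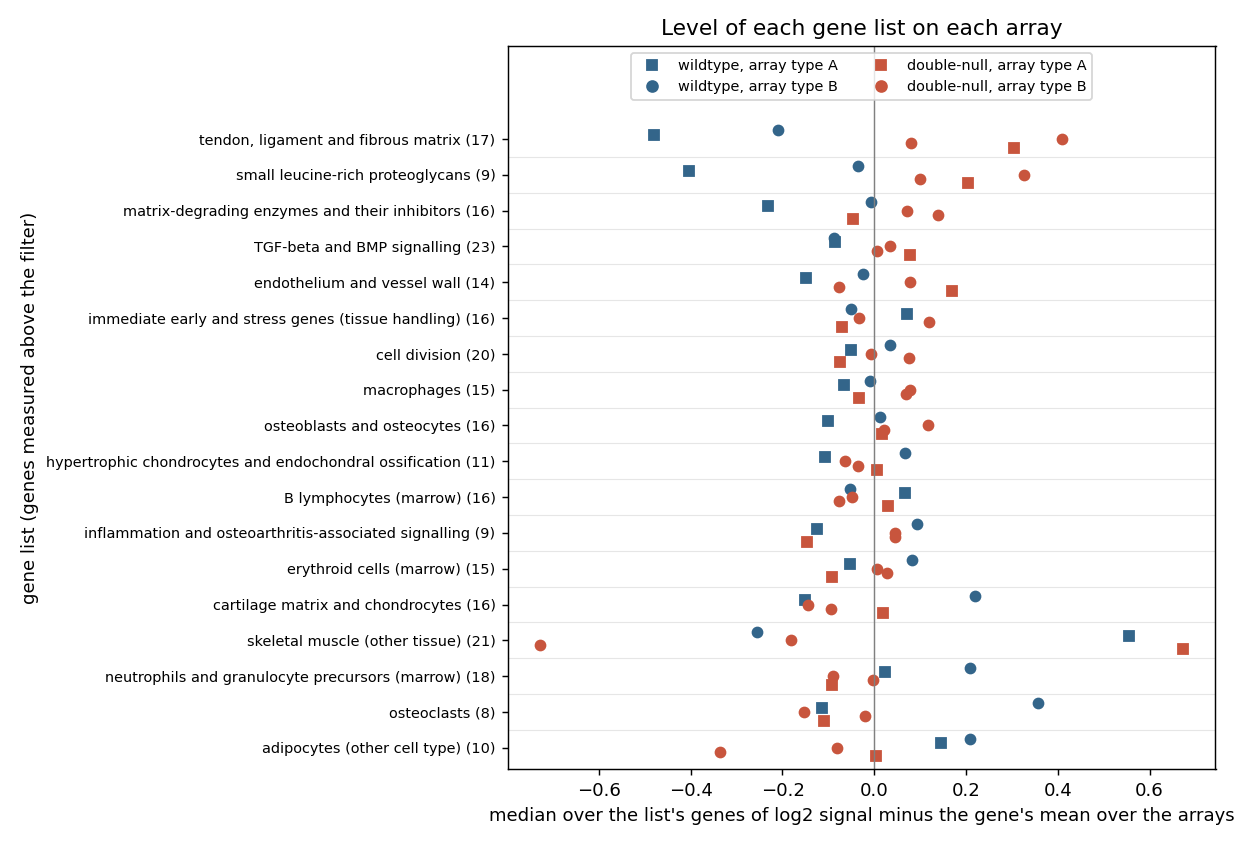
Level of each of the 18 tested gene lists on each array, as the median over its genes of log2 signal minus the gene's mean over the 5 arrays; colours give genotype, shapes give array type, and the number of genes stands in brackets. The fibrous list lies below 0 on both wildtype arrays and above 0 on the 3 double-null arrays, while the muscle list lies highest on the 2 arrays of type A.

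Arrays were alike across genes whatever the genotype. Pearson correlations across genes ran from 0.948 to 0.969, and the highest pair was wildtype pool 2 with double-null pool 3, of different genotype and the same array type. The 2 double-null pools on type B correlated at 0.965. The first principal component (34.5% of the variance) placed wildtype pools 1 and 2 and double-null pool 3 on 1 side and double-null pools 1 and 2 on the other. Signal ratios of 3' over 5' control probe sets were 0.849 and 0.888 for Gapdh on the type A arrays and 1.03 to 1.04 on type B, and 1.08 to 1.25 for Actb. For the transferrin receptor Tfrc the ratio was 6.16 in double-null pool 3 and 3.71 to 4.26 in the others.

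Genes next to the targeted genes were compared with all others, because a mixed strain background can keep a stretch of the targeted cells' chromosome. Of 33 tested genes within 10 Mb of Epyc, on the GRCm38.p6 assembly of the gene table, 7 had an unadjusted p under 0.05 (21.2%, exact Clopper-Pearson 95% interval 8.98 to 38.9%), against 6.12% of other genes (two-sided Fisher's exact p = 0.0035, and 0.014 after Benjamini-Hochberg over the 4 regions examined). The 7 were Lum, Igf1, Arl1, Dcn and Ikbip, which were higher, and Dram1 and Ndufa12, which were lower. Within 10 Mb of Bgn 2 of 38 tested genes did so, or 5.26% (95% interval 0.644 to 17.8%, Fisher's exact p = 1).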

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

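The look at probe sets without a single gene symbol was chosen after the main results were seen. These 1022 probe sets above the intensity filter take no part in the gene comparisons, and 3 of them passed the threshold in a limma fit of their own, while 60 had an unadjusted p under 0.05. The first rose by 2.03 on the log2 scale (SE 0.30, adjusted p = 0.040), at 194 and 445 on the wildtype arrays and 1220, 1527 and 1085 on the double-null arrays. Another changed by -2.56 (SE 0.27, adjusted p = 0.0089), at 458 and 1554 against 85.7, 76.2 and 149. The remaining one changed by -4.15 (SE 0.52, adjusted p = 0.017), at 498 and 2258 against 47.9, 15.4 and 17.2. These 3 lie within the range of the Bacillus controls over all arrays, so its size depends on the added constant. On double-null pool 1 itself the highest control was 31.4. In each of the 3 the wildtype arrays themselves differed by over 2-fold, with the lower value in wildtype pool 1, and no gene is named for them here.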

How the results depend on the processing

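The lists without selected members, the region beside Epyc without 3 genes and the fibrous list on array type A alone were added after the data were seen. All 9 genes past the threshold kept their direction under every alternative in which they were tested, and they passed in 15 of 16 (Bgn), 14 of 15 (Rpgrip1), 10 of 16 (Col3a1 and Serinc3), 9 of 16 (Pam), 7 of 15 (Fbln7), 5 of 16 (Lum), 4 of 16 (Fn1) and 3 of 16 (Col6a1). The count of 9 (6 higher, 3 lower) became 5 with the deposited scaling (2 higher), 2 without the filter (1 and 1), where more genes are tested, 4 without the array-type term (2 higher), and 2 on array type B alone (1 and 1), where fewer arrays are used. Median centring and no intensity trend each left 3 higher. Without single pools it ran from 2 to 52, with 1 to 40 higher and 1 to 12 lower. The pseudocount of 1 gave 11. Where not stated otherwise, the cause was not tested. Fits without 1 pool have 1 residual degree of freedom. An array left alone on its type is fitted exactly, so the fits without wildtype pool 2, without double-null pool 3 and on array type B alone are 1 contrast, counted as 3 of the alternatives, and the fit without wildtype pool 1 compares double-null pool 3 with wildtype pool 2 alone. The number of Bgn and Epyc probe sets past the threshold, 3 of 4, became 0 on array type B alone and ran from 0 to 3 without single pools. Epyc did not pass under any alternative (adjusted p 0.077 to 0.96), and its fold depended on the pseudocount, from -4.24 with the smallest to -0.67 with the largest, because its double-null signal lies at background.

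The 8 gene lists past the threshold became 5 without the filter, which lost the proteoglycan, muscle and signalling lists, and 0 with an estimated correlation. Genes with groups fully apart became 1105 above and 1342 below without the filter, where 12394 genes are counted. The share of genes beside Epyc became 13.3% without Lum, Dcn and Igf1 (exact p = 0.11), a fall by construction, since all 3 were among the 7 genes with an unadjusted p under 0.05. The proteoglycan list without the targeted genes had a median of 0.41, tested with the preset correlation only. The fibrous list was 0.69 on array type A and passed in all alternatives but the estimated correlation.

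Nothing in the labels ties pools of the same replicate number, so the numbers were treated as names only. Only 2 pairs exist, and same-numbered arrays deviated from their group means with correlations of 0.00652 and -0.18 across genes. With 2 wildtype arrays each deviation mirrors the other, so these correlations cannot show or exclude a pairing. The fit with the replicate block left out array type, since both terms together leave no residual degrees of freedom. Under the block, limma called 0 genes (0 higher, 0 lower), with 486 at unadjusted p under 0.05, and the tests of these turned: cell division (median 0.053), erythroid (-0.0054) and inflammation (0.062) lists, and Nfkbia (0.062). The osteoclast (adjusted p = 0.058) and signalling (0.24) lists did not pass under it, and the muscle median was -0.65 (adjusted p = 2.8e-09) against -0.15. The muscle level was 0.56 in wildtype pool 2 on type A and -0.26 in wildtype pool 1 on type B. The muscle value under the block therefore cannot be read as a shift with genotype.

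Reversals otherwise concerned results that had not passed, apart from muscle. The cell division test turned with the deposited scaling (median 0.045), median centring (0.083), no array-type term (0.046) and the mean over probe sets (0.034), which also turned the B lymphocyte test (0.0092). The endothelial list was -0.041 and Col10a1 -0.40 on array type B alone, and the inflammation list was 0.028 without the filter. Without single pools the list medians ran from -0.40 to 0.30 for cartilage, -0.26 to 0.15 for muscle, -0.041 to 0.33 for endothelium, -0.16 to 0.070 for hypertrophic cartilage, -0.030 to 0.15 for immediate early genes, -0.047 to 0.012 for erythroid genes and -0.013 to 0.034 for cell division. Single genes ran from -0.62 to 0.049 for Acta1, -0.42 to 0.051 for Ccna2, -0.78 to 0.21 for Cd79a, -0.94 to 0.17 for Ckm, -0.65 to 0.27 for Clcn7, -0.40 to 1.65 for Col10a1, -0.52 to 0.092 for Epor, -0.13 to 0.73 for Ier3, -1.06 to 0.19 for Pth1r, -0.038 to 0.43 for Slc4a1 and -0.10 to 0.38 for Vwf, in all but Col10a1 turning without wildtype pool 1.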

Other observations

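The genes in the next paragraph were chosen after their values were seen, as were the tests of the fibrous list and of the regions around Rpgrip1 and Serinc3.

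The genes that follow missed the threshold and were not tested as a group. Dpt, encoding dermatopontin, a small matrix protein that binds proteoglycans, read 1388 ± 93.2 in double-null (n = 3) and 667 ± 33.3 in wildtype pools (n = 2), with limma adjusted p = 0.050, not under 0.05 before rounding. The syndecan gene Sdc2 read 611 ± 115 against 281 ± 52.7 (adjusted p = 0.10), the versican gene Vcan 202 against 101 (adjusted p = 0.22), and Abi3bp 501 ± 164 against 212 ± 54.1 (adjusted p = 0.21). Among genes of other kinds, the mitochondrial protein gene Ghitm read 1664 ± 16.2 against 749 ± 203 and the purine nucleoside phosphorylase gene Pnp 2394 ± 342 against 1194 ± 182 (both adjusted p = 0.054). The neuropeptide Y gene Npy read 509 ± 56.7 against 245 ± 2.24 (adjusted p = 0.060), and the growth factor gene Igf1 529 ± 151 against 251 ± 84.5 (adjusted p = 0.10). Igf1 lies beside Epyc, so its value has the same limit as that of Lum, and Pnp lies within 10 Mb of Rpgrip1. The sorting receptor gene Sorl1 lay lower, at 1018 ± 84.3 against 1766 ± 17.7 (adjusted p = 0.14).

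The fibrous matrix list was higher in the double-null pools, a shift that passed with the preset correlation and not with an estimated one (camera adjusted p = 1.4e-14 and 0.45). A difference between the array types is argued against, since the lower of its medians on a single type was 0.50 (95% bootstrap interval 0.10 to 0.997). That check was chosen after the list was seen to be higher. A smaller share of marrow would raise cartilage, muscle and fat genes alike. The fibrous median lay 0.73 above that of their 47 members (interval over genes, not pools, 0.33 to 1.17). The list medians were seen before this comparison was chosen, so a difference above 0 was known and is described, not tested. On array type A the medians were 0.69 for fibrous, 0.28 for cartilage, 0.15 for muscle and -0.17 for fat genes. On type B they were 0.50, -0.40, -0.26 and -0.34. The fibrous list lay highest on both types, each with a single wildtype pool, but cartilage and muscle changed sign between them. As a description of these arrays, the values go against marrow share only as the whole cause, and a part was not excluded. Of the marrow lists the neutrophil one was lower (-0.19), and the erythroid (-0.043) and B lymphocyte (-0.035) ones did not pass. More tendon and ligament in the dissected double-null joints may explain the shift and cannot be told apart from a change within the same tissue. The 4 measured markers picked for this check, none of them collagens, had a median of 0.59 with an interval of -0.32 to 1.03 (Tnmd 1.03, Thbs4 1.02, Fmod 0.17, Angptl7 -0.32). All but Fmod belong to the fibrous list itself. The list's other members that are not collagens ran from -0.10 (Tnc) to 0.70 (Pcolce). Col1a1 and Col1a2, of the osteoblast list, were at -0.039 and -0.063. These values cannot decide the question, and loss of biglycan and epiphycan itself stays open as an untested biological hypothesis.

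Rpgrip1, Serinc3 and Pam belong to none of the gene lists, and whether they have a tie to the joint was not examined. A strain variant under the probes may account for their changes. For Serinc3 the 2 other probe sets above the filter were lower too (-1.44 and -1.38), with a ratio to the named probe set of up to 0.847, which argues against an effect on a single probe set, although overlap between the probe sets' sequences was not examined. Rpgrip1 and Pam each had 0 other probe sets above the filter, so a difference under a single probe set cannot be told apart from a change in their transcripts. A stretch of another strain carrying many differing genes could not be shown or excluded: within 10 Mb of Rpgrip1 6.67% of 90 tested genes had an unadjusted p under 0.05 and within 10 Mb of Serinc3 5.05% of 99, against 6.17% and 6.19% elsewhere. The genotype itself stays open for all 3 genes.

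The genes beside Epyc differed more often than others, at 21.2% of 33 against 6.12%, which is consistent with a stretch of the targeted cells' strain kept beside Epyc. Without Lum, Dcn and Igf1 the share was 13.3% (Fisher's exact p = 0.11). That fall is by construction and cannot tell the region from the tissue, so whether a change of the tissue adds to the excess stays open. Lum is both the fourth largest rise among called genes and a neighbour of Epyc, so its rise cannot be assigned to the tissue or to the region from these arrays. Beside Bgn the share was 5.26% of 38 (interval 0.644 to 17.8%), too wide to exclude or show such a stretch.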
